A study of Mus musculus with 8 samples.

How the data were processed

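The data are 8 RNA sequencing libraries of mouse embryonic stem cells in 4 groups of 2, taken after 6 days without LIF. Per the labels' protocols, 2.5 µg/ml doxycycline was added daily, cells were at passages 8 to 15, RNA was taken from whole cells in TRIzol, and libraries were made with the NEBNext Ultra Directional RNA kit after depletion of ribosomal RNA. The protocol text is the same for all groups, noDox included. The labels also give E14 the cell description of the inducible AGO2 line while naming its genotype wild type.

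Per the submitters' processing notes, bcl2fastq 2.17.1, TopHat and Cuffdiff were used with the mouse build mm10 (GRCm38), with no version for the other tools and no statement of the annotation or of how strand was used. Each deposited comparison table gives RPKM values, per the file headers, as 1 value per group, with no value per library. The test statistic (a signed score), the p-value and the q-value of each gene were also made by the authors, per the file headers. A deposited summary table holds log2 folds per the file headers. They equal the log2 of (group RPKM + 0.1) over (noDox RPKM + 0.1) within 0.01 for 100% of 24251 matched genes, with the noDox values of the first table in every column. For NLS the summary thus mixes 2 scalings, since only 31.9% of its values follow the NLS table's own noDox values, and it was not used for results. Values shown in place of numbers by the spreadsheet program were read as minus infinity in the statistic. Some gene symbols had been turned into dates and were left as they were. Reads of near-identical genes, of overlapping genes and of short RNA genes within longer transcripts are uncertain, since the counting is not described.

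The tables named noDox against DOX and noDox against E14 were identical in 24279 of 24279 lines. Both names are therefore given, and results planned for DOX and for E14 are the same values. The noDox values of the NLS table were 1.03 times those of the first table (5th to 95th percentile 1.02 to 1.03 over 12067 genes), because each table was scaled on its own. Some items are withheld and are not reported here.

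Log2 folds were computed from the RPKM values with no pseudocount. The SE of a log2 fold is the absolute log2 fold divided by the absolute test statistic. The p-values imply a z that is 1.41 times the statistic in the DOX/E14 table and 1.42 times in the NLS table (medians), close to the square root of 2, so for most genes this SE is larger than the one behind the p-values. The reverse held for 455 of 8607 genes with a p above the lowest in the DOX/E14 table and 162 of 12425 in the NLS table, whose statistic was larger than p implies and whose SE is too small by that measure. The lowest p in either table is 5e-05, which gives a lowest q of 0.00017 in the DOX/E14 table and 0.00191 in the NLS table. A gene is called changed at q < 0.05 in the authors' deposited table, which matched the tables' own significance column in 24279 lines of each. Genes at 0 in a group have no finite fold and are given as values. In list medians and their percentiles a tested gene of this kind counted as above or below every finite fold. As only group values were used, no model was refitted and no library could be left out. The analysis plan had named FPKM as the likely unit; the values are RPKM, per the file headers, and the planned test stays the same.

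Differences between the NLS and DOX/E14 folds were tested with a z whose variance is the sum of both squared SEs, which counts the noDox variance although it cancels, with a two-sided normal p and Benjamini-Hochberg adjustment over 11907 genes. This test was tried on simulated data with 200 changed genes. Agreement between the tables was set beside 100 simulations of unchanged groups with a shared control and beside the overlap of independent lists. The tests, the rule for named genes and the lists were fixed before the data were examined. The lists were Argonautes, microRNA machinery, naive, general and primed pluripotency, primitive streak and mesoderm, definitive endoderm, extraembryonic endoderm, neuroectoderm, trophoblast, 2-cell-like, germ cell, cardiac, blood and endothelium, fibroblast and mesenchyme, Hox, LIF-STAT3, Wnt targets, miR-290/miR-302 targets, let-7 targets, p53 targets, integrated stress, interferon, imprinted, cell cycle, DNA methylation and Polycomb, replication-dependent histones, mitochondrial genes, ribosomal proteins and short RNAs. Of the Argonaute list 1 of 3 tested genes fell in the DOX/E14 table and 1 of 2 rose in the NLS table. Each list's median log2 fold was placed among 10000 random lists of tested genes of the same size, matched on 10 classes of mean RPKM, and called apart below percentile 2.5 or above 97.5. In 200 trial lists drawn at random 9 fell outside these limits. Lists with fewer than 3 tested members have no percentile.

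Named genes are the Argonautes, the 5 largest rises and 5 largest falls per comparison among called genes with at least 0.1 RPKM in both groups and a mean of at least 5 RPKM, up to 4 called members per list with the largest folds and at least 1 RPKM in a group (2 by expression where none was called), and the 5 largest differences each way. Differences were ranked among genes that passed their test with at least 0.1 RPKM in noDox, DOX/E14 and NLS. A mean of at least 5 RPKM over DOX/E14 and NLS was also required. Genes named by number or clone alone were skipped in the rankings. The Y-linked genes were added after their values were seen. Coordinates come from GENCODE M21 on GRCm38, which holds 23153 of the 24277 gene symbols.

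The alternatives were q under 0.01, an absolute log2 fold of at least 1, adjustment recomputed from the deposited p-values, a floor of 1 RPKM, median-centred folds, normal p-values of the statistic, leaving out short RNA genes, removing the noDox variance, and pseudocounts of 0.1 and 1. Alternatives that scale the statistic by the square root of 2, subtract a share of the DOX/E14 values from NLS, or use an SE at least as large as p implies were added after the data were seen. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used.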

Results

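RNA was measured by sequencing in 8 libraries of mouse embryonic stem cells, cultured cells derived from the early embryo that can form all tissues of the body. The cells had been grown for 6 days without leukemia inhibitory factor (LIF), the cytokine that holds such cells in the undifferentiated state. The libraries fell into 4 groups of 2. The labels describe noDox as cells lacking Argonaute 1 to 4, the proteins that carry microRNAs to their target transcripts. DOX is described as such cells expressing only AGO2 from a doxycycline-inducible transgene, and NLS as such cells expressing only AGO2 with a nuclear localization signal. E14 is described as the wild-type cells. The study's question, per its title, was whether Argonaute-dependent silencing by microRNAs in the nucleus is needed for differentiation.

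The comparison tables give 1 RPKM value per group (reads per kilobase of transcript, scaled to the depth of the library), pooled over 2 libraries, together with a test statistic, p and q for each group against noDox. Every error quoted here is therefore the standard error (SE) that the deposited statistic implies for the log2 fold, and no spread between libraries can be given. The tables held 24279 genes, of which 12382 were tested in the first comparison and 12936 in the NLS comparison. The depth of the libraries is unknown. Among the 3986 untested genes with a value in both groups of the first comparison, the most frequent ratio recurred in 64. Counts of reads were not given, so the worth of a single read was not recovered.

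All 24279 lines of the table named noDox against E14 were identical to those of the table named noDox against DOX. The files thus hold 2 distinct comparisons, not 3, and the values of the first belong either to the DOX or to the E14 libraries. They are reported below as those of the group labelled DOX or E14.

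Ago1 stood at 0.0159 RPKM in noDox, 16.7 RPKM in the group labelled DOX or E14, and 0.861 RPKM in NLS. The log2 fold of 10.03 (SE 2.32) in the DOX/E14 table did not pass q < 0.05 (q = 0.233 in the authors' deposited table), and Ago1 was not tested in the NLS table. An Ago1 value of this size goes against the DOX label, which describes cells with AGO2 alone, so every direction drawn from that table rests on an unsettled group name. Ago2 was at 26.1 RPKM in noDox, 32.6 in DOX/E14 and 35.7 in NLS, and neither difference passed the test. These gene-level values do not separate the endogenous gene from a transgene or the deleted exons from those that remain. Ago3 fell from 7.56 to 3.001 RPKM in the DOX/E14 table (log2 fold −1.33, SE 0.29) and rose from 7.76 to 14.5 RPKM in the NLS table (log2 fold 0.90, SE 0.32). Ago4 was at or below 0.323 RPKM in every group and was not tested. On GRCm38 (mm10) Ago3 (chromosome 4, 126331704 to 126429556), Ago1 (126435012 to 126468583) and Ago4 (126489541 to 126533472) lie side by side on the minus strand, and Ago2 lies on chromosome 15 (73095844 to 73184935).

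The Y-linked genes were chosen after their values were seen. Ddx3y was listed at 0 RPKM in noDox, 11.1 in DOX/E14 and 0.311 in NLS, and Uty at 0, 7.66 and 0.168 RPKM. Eif2s3y was at 0.0348, 24.5 and 0.492 RPKM.

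**Figure D1:**
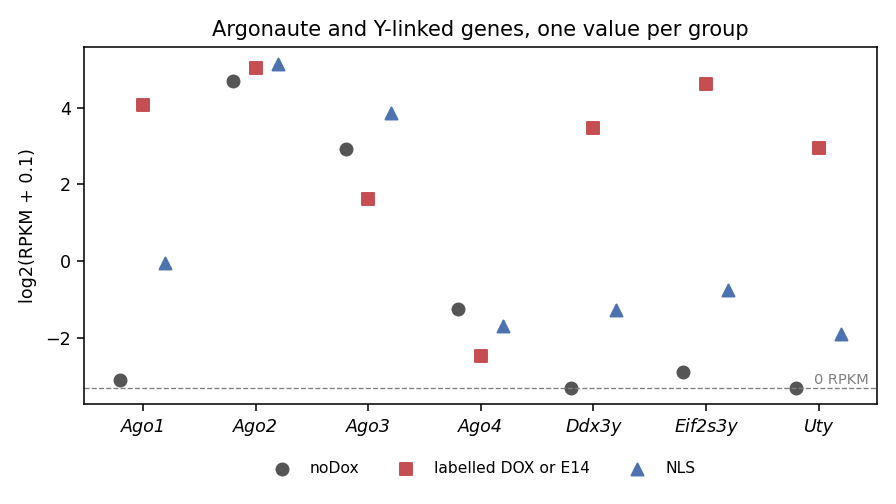
Values of the 4 Argonaute genes and 3 Y-linked genes as log2(RPKM + 0.1), 1 point per group pooled over 2 libraries, with a dashed line at 0 RPKM. Ago1 and the Y-linked genes are high in the group labelled DOX or E14, at or near 0 in noDox, and low but above noDox in NLS.

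The DOX/E14 table asked what differs between cells described as having Argonaute and cells described as lacking it, after 6 days without LIF. The groups also differed in Y-linked RNA, and Ago2 and Ago3 RNA were present in noDox, so the changes cannot be assigned to Argonaute apart from other differences between the lines. At q < 0.05 in the authors' deposited table, 6878 of 12382 tested genes changed: 3368 rose and 3510 fell relative to noDox. With an absolute log2 fold of at least 1 required as well, 3897 genes remained, 1666 higher and 2231 lower. The median log2 fold of genes with at least 1 RPKM in both groups was 0.035.

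The largest rises among well expressed genes included Mid1, a microtubule-associated ubiquitin ligase on the X chromosome, which rose from 0.219 to 43.4 RPKM. Lin28a, an RNA-binding protein of the pluripotent embryo that blocks let-7 maturation (chromosome 4, 134003330 to 134018841), rose from 1.35 to 248 RPKM, a log2 fold of 7.52 (SE 0.39). Phlda2 and Cdkn1c, both imprinted growth regulators, rose to 78.2 and 41.3 RPKM from 0.504 and 0.316. Pou3f1, a transcription factor of the post-implantation epiblast, rose from 0.115 to 15.5 RPKM. The largest falls were those of Plagl1, an imprinted zinc-finger gene (chromosome 10, 13060504 to 13131694), from 60.1 to 0.145 RPKM, and of Mir6236, a short RNA gene, from 636419 to 2273 RPKM. Mir6236 alone thus held a large part of the noDox RPKM sum of 1.2552e+06. The source of its reads was not tested, so its fall cannot be read as a change of this gene. Copz2, a coat protein gene, fell from 68.1 to 0.374 RPKM, and Hhip, an inhibitor of Hedgehog signalling, from 46.8 to 0.332 RPKM. Lars2, the mitochondrial leucyl-tRNA synthetase gene, was called lower (5777 to 24.1 RPKM) although its implied SE of 10.22 exceeded its log2 fold of −7.90. Its log2 folds in the DOX/E14 and NLS tables (−7.90 and −4.77) lay near those of Mir6236 (−8.13 and −4.43). The source of the Lars2 reads was not tested either, so the same limit holds.

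Genes of naive pluripotency fell. Of 18 tested members 14 fell, 1 rose and 3 did not pass, and the counts were the same when adjusted over the list alone. The list's median log2 fold was −1.40, below all 10000 random lists matched on expression. Prdm14 (chromosome 1, 13113457 to 13127163) fell from 34.1 to 1.24 RPKM (log2 fold −4.78, SE 0.42), Tbx3 from 49.6 to 2.80, Klf4 from 32.7 to 3.19 and Klf2 from 316 to 38.2 RPKM. These 4 encode transcription regulators of the naive state. Of 12 tested LIF-STAT3 genes 4 rose and 5 fell, the same when adjusted over the list alone, with a median log2 fold of 0.05 at percentile 47.4. Tfcp2l1, a STAT3 target, fell from 99.5 to 14.01 RPKM, and the receptor genes Il6st and Lifr fell from 77.0 to 14.3 and from 31.9 to 8.14 RPKM. Among 9 general pluripotency factors 4 rose and 2 fell, also when adjusted over the list alone (percentile 64.8). Sox2 fell from 184 to 53.2 and Gdf3 from 98.2 to 46.3 RPKM, whereas Dnmt3l, a cofactor of the de novo DNA methyltransferases, rose from 78.8 to 326 RPKM.

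Genes of the primed epiblast stood apart in the other direction. Of 13 tested members 6 rose and 3 fell, the same when adjusted over the list alone, and the median log2 fold of 1.96 lay above all matched lists. Dnmt3b, a de novo DNA methyltransferase, rose from 19.3 to 322 RPKM (log2 fold 4.06, SE 0.29), Sfrp2 from 2.50 to 14.3 and Sox3 from 0.496 to 3.47 RPKM. Among 11 tested genes of DNA methylation and Polycomb complex 2, 6 rose and 4 fell, also when adjusted over the list alone (percentile 83.9). Dnmt3a rose from 10.1 to 32.8 RPKM and Tet3 fell from 10.9 to 4.05 RPKM.

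Lineage markers moved in both directions. In neuroectoderm 7 of 9 tested genes rose and 0 fell, also when adjusted over the list alone, with 7 at an unadjusted Cuffdiff p under 0.05 (median log2 fold 1.86, percentile 99.97). Sox11 rose from 0.659 to 10.4 RPKM, Nes, the intermediate filament of neural progenitors, from 2.86 to 19.05 RPKM, Sox1 from 0.351 to 5.05 and Pax6 from 0.438 to 2.85 RPKM. Of 10 primitive streak and mesoderm genes 4 rose and 3 fell, the same when adjusted over the list alone (median 2.03, percentile 100). Over the 7 members tested with finite folds in both tables, the DOX/E14 median was 0.59. Wnt3 rose from 0.128 to 6.76 RPKM and Bmp4 from 1.27 to 6.30, whereas Kdr fell from 1.59 to 0.120 and Evx1 from 3.27 to 0.281 RPKM. Of 6 definitive endoderm genes 1 rose and 4 fell, also when adjusted over the list alone (median −1.09, percentile 2.79), with Prdm1 from 25.4 to 2.09 RPKM, Cxcr4 from 2.28 to 0.301 and Otx2 from 25.7 to 11.4 RPKM. Of 11 extraembryonic endoderm genes 7 rose and 2 fell, the same when adjusted over the list alone (percentile 90.3). Serpinh1, a collagen chaperone, rose from 11.8 to 49.4 RPKM, and Lamc1 fell from 132 to 46.0 RPKM.

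Among 10 trophoblast genes 4 rose and 3 fell (5 and 3 when adjusted over the list alone, percentile 95.4). Krt18 rose from 45.8 to 270 RPKM, and Tead4 and Esx1 fell from 27.4 to 5.15 and from 9.32 to 1.69 RPKM. Of 11 germ cell genes 4 rose and 5 fell, the same when adjusted over the list alone (percentile 39.0). Ddx4 rose from 2.77 to 10.9 RPKM and Dppa3 from 1.40 to 8.41 RPKM. Of 9 fibroblast and mesenchyme genes 5 rose and 2 fell (6 and 2 when adjusted over the list alone), with a median log2 fold of 5.15 above all matched lists. Over the 6 members tested with finite folds in both tables, the DOX/E14 median was 0.66. The larger median thus rests on members outside that set. Tagln and Acta2, genes of the contractile cytoskeleton, rose from 5.77 to 205 and from 0.339 to 31.4 RPKM, Vim rose from 28.5 to 85.5 and Fstl1 fell from 87.7 to 39.7 RPKM. Of 4 blood and endothelial genes 1 rose and 3 fell, also when adjusted over the list alone (percentile 1.37). Pecam1 fell from 86.8 to 13.9 RPKM and Gata1 from 3.75 to 0.361 RPKM. Of 4 cardiac genes 1 rose, the same when adjusted over the list alone (percentile 99.8), namely Actc1, which was listed at 0 in noDox and stood at 10.1 RPKM. The median of 5 tested Hox genes lay at percentile 0.065. Among them Hoxd8 fell from 3.01 to 0.112 RPKM, a call that also held when adjusted over the list alone. Among 4 tested genes of the 2-cell-like state 1 rose and 1 fell, the same when adjusted over the list alone (percentile 0.48). Zscan4a fell from 1.98 to 0.174 RPKM, a value that is uncertain because the Zscan4 copies are nearly identical.

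The fixed lists of microRNA targets moved in opposite directions. Of 10 tested targets of the miR-290/miR-302 seed family 8 fell and 1 rose (8 and 2 when adjusted over the list alone), and the median log2 fold of −1.69 lay below all matched lists. Rbl2, a retinoblastoma family gene, fell from 13.5 to 1.38 RPKM (log2 fold −3.30, SE 0.60). The Nodal antagonists Lefty2 and Lefty1 fell from 102 to 16.5 and from 489 to 109.5 RPKM, and Ei24 fell from 180 to 37.8 RPKM. Of 20 let-7 targets 14 rose and 1 fell, also when adjusted over the list alone (median 0.98, percentile 99.99). After Lin28a, the largest rises were those of Myc, from 2.16 to 30.9 RPKM, Hmga1, from 2.22 to 8.72, and Ccnd1, from 23.0 to 73.2 RPKM. Among 14 genes of microRNA biogenesis and silencing 2 rose and 6 fell, the same when adjusted over the list alone (percentile 39.5). Mov10, an RNA helicase, fell from 301 to 24.98 RPKM, and Tnrc6b and Tnrc6c, which encode the GW182 partners of Argonaute, fell from 17.7 to 5.70 and from 25.2 to 9.99 RPKM. Cnot6l, a deadenylase, fell from 10.96 to 4.63 RPKM.

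Proliferation genes rose in the DOX/E14 table. Of 17 tested members 14 rose and 0 fell, also when adjusted over the list alone, and 14 had an unadjusted Cuffdiff p under 0.05 (median 0.78, percentile 97.7, and 97.45 among members with at least 1 RPKM). Plk1 rose from 36.4 to 96.1 RPKM, Ccne1 from 41.5 to 109.1, Ccnb1 from 34.0 to 86.4 and Pcna from 115 to 280 RPKM. Of 8 Wnt targets 5 rose and 1 fell, the same when adjusted over the list alone (median 5.21, percentile 100). Over the 5 members tested with finite folds in both tables, the DOX/E14 median was 1.69. Axin2 rose from 0.395 to 8.29 RPKM and Tcf7 from 4.54 to 14.6, whereas Notum fell from 25.6 to 2.95 RPKM. Of 14 integrated stress response genes 9 rose and 2 fell, also when adjusted over the list alone (median 1.29, percentile 100). They included the serine synthesis gene Phgdh, from 7.12 to 70.1 RPKM, Mthfd2, from 14.5 to 80.6, Chac1, from 1.25 to 11.99, and Trib3, from 3.86 to 19.6 RPKM. The p53 targets split, with 6 rises and 6 falls among 16, the same when adjusted over the list alone (percentile 38.1). Perp and Plk2 rose from 13.2 to 37.8 and from 14.3 to 35.0 RPKM, and Pmaip1 and Sesn1 fell from 15.9 to 7.02 and from 8.79 to 3.59 RPKM. Of 8 interferon-stimulated genes 1 rose and 5 fell, also when adjusted over the list alone (median −1.41, percentile 0.88). Oas1a fell from 17.5 to 0.567 RPKM, Irf9 from 20.5 to 3.20 and Oasl2 from 4.71 to 0.381, while Bst2 rose from 33.6 to 91.3 RPKM.

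Of 21 tested imprinted genes 7 rose and 9 fell, the same when adjusted over the list alone (median −0.22, percentile 13.5). Besides Plagl1, Phlda2 and Cdkn1c, Igf2, a fetal growth factor (chromosome 7, 142650766 to 142666816), rose from 0.947 to 42.4 RPKM (log2 fold 5.49, SE 0.41). Of 78 ribosomal protein genes 31 rose and 5 fell (25 and 5 when adjusted over the list alone, percentile 59.0). Rpl7l1 and Rps2 rose from 33.6 to 92.9 and from 38.5 to 100.5 RPKM, and Rpl10l fell from 104 to 20.5 RPKM. Of 275 tested genes of the short RNA list 1 rose and 8 fell (1 and 3 when adjusted over the list alone, median 0.04, below all matched lists). The 1 rise was that of Mir17hg, the host transcript of the miR-17/92 cluster, from 11.95 to 41.8 RPKM. Mirg, a transcript of the imprinted cluster on chromosome 12, fell from 10.2 to 0.673 RPKM. The list took every symbol starting with Mir, so it also held longer transcripts. Mir17hg, Mirg and Mir124a-1hg, which also fell, are annotated as lincRNA. Genes of this list took 73.8% of the RPKM sum in noDox and 51.4% in DOX/E14, a fall carried by Mir6236 alone, since without this gene they took 46.9% and 51.2%.

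The NLS comparison asked what AGO2 carrying a nuclear localization signal changes in cells described as lacking the other Argonautes. At q < 0.05 in the authors' deposited table, 1081 of 12936 tested genes changed, with 513 rises and 568 falls. At q under 0.01 the count was 531, and 642 genes passed with an absolute log2 fold of at least 1. The median log2 fold of expressed genes was −0.022. Lin28a showed the largest rise among well expressed named genes, from 1.39 to 30.5 RPKM (log2 fold 4.45, SE 0.50, q = 0.00191 in the authors' deposited table, the lowest q that table holds). Myl9, a regulatory myosin light chain, rose from 0.876 to 13.1 RPKM, Nkx2-9, a homeobox gene, from 0.729 to 9.36, Serpine2, a protease inhibitor, from 1.43 to 15.7, and Ltb4r1, a leukotriene receptor, from 0.883 to 9.21 RPKM. Mir6236 fell from 656380 to 30366 RPKM, where the same limit on the source of its reads holds. Copz2 fell from 69.8 to 10.6 RPKM, Scnn1a, a sodium channel subunit, from 11.8 to 1.83, Hypk from 30.3 to 6.01 and Lgals9, a galectin, from 85.6 to 17.3 RPKM.

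In the NLS table, of 17 tested naive pluripotency genes 1 rose, 2 fell and 14 did not pass (1 and 3 when adjusted over the list alone, percentile 62.9). Klf4 rose from 33.5 to 51.6 RPKM (log2 fold 0.62, SE 0.30), whereas Prdm14 fell from 35.0 to 14.2 (log2 fold −1.30, SE 0.34) and Klf2 from 324 to 153 RPKM. Of 10 general pluripotency factors 3 rose and 0 fell, also when adjusted over the list alone, with 3 at an unadjusted Cuffdiff p under 0.05 (percentile 93.4). Besides Lin28a, Dnmt3l rose from 80.8 to 221 RPKM and Zfp281 from 16.3 to 25.6 RPKM. Of 12 primed epiblast genes 1 rose and 1 fell (2 and 1 when adjusted over the list alone, median 0.48, percentile 98.7), namely Dnmt3b, from 19.8 to 30.8 RPKM, and Otx2, from 26.4 to 16.4 RPKM. For Dnmt3b, noDox plus 4.95% of the DOX/E14 value, the share that Ago1 RNA reached in NLS, would give 36.1 RPKM, above the NLS value. Of 11 DNA methylation and Polycomb genes 2 rose and 0 fell, the same when adjusted over the list alone, with 2 at an unadjusted Cuffdiff p under 0.05 (percentile 97.3). Among 12 LIF-STAT3 genes 2 rose and 1 fell (3 and 1 when adjusted over the list alone, percentile 94.7). Junb rose from 13.3 to 22.9 RPKM and Il6st fell from 79.0 to 43.4 RPKM.

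Genes of the p53 response rose in the NLS table. Of 16 tested members 9 rose and 0 fell, or 12 and 0 when adjusted over the list alone, and 12 had an unadjusted Cuffdiff p under 0.05. The median log2 fold of 0.75 lay above all matched lists. Perp rose from 13.6 to 52.6 RPKM (log2 fold 1.95, SE 0.35), Plk2 from 14.7 to 42.5, Mdm2, the ubiquitin ligase that limits p53, from 28.1 to 80.3, and Zmat3 from 18.8 to 43.3 RPKM. Of 13 integrated stress genes 2 rose and 0 fell (3 and 0 when adjusted over the list alone, 4 at an unadjusted Cuffdiff p under 0.05, percentile 81.2). Atf3 rose from 1.12 to 7.83 and Trib3 from 3.96 to 8.56 RPKM. Proliferation genes gave 0 calls among 17, also when adjusted over the list alone, and 0 at an unadjusted Cuffdiff p under 0.05 (percentile 63.1). Mcm7 stood at 169.5 and 159.5 RPKM in noDox and NLS, and Mcm5 at 119 and 134 RPKM.

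Of 11 tested 2-cell-like genes 4 rose and 0 fell (6 and 0 when adjusted over the list alone), and 8 had an unadjusted Cuffdiff p under 0.05. The median log2 fold was 2.15, above all matched lists. Zscan4a (chromosome 7, 10794242 to 10799057, annotated as an unprocessed pseudogene) rose from 2.03 to 13.3 RPKM (log2 fold 2.71, SE 0.53). Zscan4d rose from 1.97 to 12.6, Zscan4c from 0.743 to 3.95 and Gm8300 from 1.46 to 7.96 RPKM. The reads of these near-identical copies cannot be placed on single genes with certainty. The counts and the percentile of this list therefore do not rest on independent genes. Only 4 members were tested in the DOX/E14 table, so most of the 11 were tested in NLS alone. Of 10 extraembryonic endoderm genes 5 rose and 0 fell (5 and 1 when adjusted over the list alone, 6 at an unadjusted Cuffdiff p under 0.05, percentile 99.98). The basement membrane genes Lama1, Col4a1 and Lamb1 rose from 1.41 to 7.77, from 8.28 to 18.7 and from 29.4 to 56.8 RPKM, and Serpinh1 rose from 12.1 to 22.5 RPKM. Of 10 trophoblast genes 3 rose and 2 fell (3 and 3 when adjusted over the list alone, percentile 99.96). Krt18 rose from 47.0 to 100.3 RPKM, Gata3 from 1.41 to 3.80 and Bmp8b from 2.59 to 5.47, and Esx1 fell from 9.55 to 3.31 RPKM.

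Of 8 neuroectoderm genes 3 rose and 0 fell (5 and 0 when adjusted over the list alone, 6 at an unadjusted Cuffdiff p under 0.05, percentile 99.1). Neurod1 rose from 0.840 to 3.30 RPKM, Sox11 from 0.677 to 1.60 and Nefl from 13.8 to 27.1 RPKM. None of 9 primitive streak and mesoderm genes passed over all genes tested, 4 rose and 0 fell when adjusted over the list alone, and 4 had an unadjusted Cuffdiff p under 0.05. Their median log2 fold of 1.20 at percentile 99.1 was 0.68 at percentile 91.8 among members with at least 1 RPKM. Tbx20 was at 3.49 and 8.44 RPKM and Evx1 at 3.35 and 2.13 RPKM in noDox and NLS. Of 6 definitive endoderm genes 0 rose and 3 fell, also when adjusted over the list alone (3 at an unadjusted Cuffdiff p under 0.05, percentile 1.15). Prdm1 fell from 26.1 to 14.4 and Trh from 72.8 to 45.2 RPKM. Of 7 fibroblast and mesenchyme genes 4 rose and 0 fell, the same when adjusted over the list alone (4 at an unadjusted Cuffdiff p under 0.05, percentile 99.8). Tagln rose from 5.92 to 44.3 RPKM, Acta2 from 0.348 to 2.51, Fbn1 from 2.22 to 4.66 and Vim from 29.3 to 53.4 RPKM. Of 5 blood and endothelial genes 1 rose and 1 fell (1 and 2 when adjusted over the list alone, percentile 93.8). Tek, an angiopoietin receptor, rose from 5.48 to 14.5 and Pecam1 fell from 89.1 to 52.1 RPKM. Of 2 tested cardiac genes Actc1 rose, from a listed 0 to 1.03 RPKM, also when adjusted over the list alone, and Myl7 was at 2.00 and 1.67 RPKM. Among 11 germ cell genes 0 rose and 2 fell (2 and 2 when adjusted over the list alone, 5 at an unadjusted Cuffdiff p under 0.05, percentile 64.5). None of 9 Hox genes passed, also when adjusted over the list alone, with 3 at an unadjusted Cuffdiff p under 0.05 (percentile 89.0). Hoxd8 was at 3.08 and 2.12 and Hoxd9 at 2.50 and 1.11 RPKM in noDox and NLS.

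Of 11 miR-290/miR-302 targets 0 rose and 2 fell in the NLS table, also when adjusted over the list alone, with 2 at an unadjusted Cuffdiff p under 0.05 (median −0.26, percentile 7.58). Lefty1 fell from 501 to 261 RPKM and Casp2 from 28.3 to 16.6 RPKM. Of 20 let-7 targets 2 rose and 2 fell (4 and 2 when adjusted over the list alone, percentile 98.1). Besides Lin28a, Ccnd2 rose from 2.08 to 7.37 RPKM, and Plagl2 and Igf2bp2 fell from 8.91 to 4.37 and from 38.7 to 22.4 RPKM. Of 14 microRNA pathway genes 0 rose and 2 fell, the same when adjusted over the list alone (2 at an unadjusted Cuffdiff p under 0.05, percentile 57.0). Mov10 fell from 309 to 138 RPKM and Dis3l2, an exonuclease of let-7 precursors, from 13.2 to 6.67 RPKM. Of 5 Wnt targets 2 rose and 0 fell (3 and 0 when adjusted over the list alone, 3 at an unadjusted Cuffdiff p under 0.05, percentile 98.8), namely Axin2, from 0.405 to 1.80, and Tcf7, from 4.66 to 8.95 RPKM. Of 9 interferon-stimulated genes 0 rose and 2 fell (0 and 4 when adjusted over the list alone, 4 at an unadjusted Cuffdiff p under 0.05, percentile 0.18), namely Oas1a, from 17.9 to 5.80, and Irf9, from 21.0 to 8.83 RPKM.

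Of 21 imprinted genes 4 rose and 1 fell in the NLS table (5 and 1 when adjusted over the list alone), with a median log2 fold of 0.45 above all matched lists. H19, a noncoding RNA (chromosome 7, 142575529 to 142578143), rose from 7.01 to 41.1 RPKM (log2 fold 2.55, SE 0.38) and its neighbour Igf2 from 0.971 to 7.35 RPKM. Grb10, a growth inhibitor, rose from 4.37 to 9.53 RPKM (below the 11.1 RPKM that noDox plus the same share of its DOX/E14 value would give), and Plagl1 fell from 61.6 to 31.1 RPKM. Of 78 ribosomal protein genes 0 rose and 5 fell, also when adjusted over the list alone (14 at an unadjusted Cuffdiff p under 0.05, median −0.20, percentile 2.40, and 2.67 with pseudocount 0.1). Rps26 fell from 1201 to 359 RPKM, Rpl41 from 959 to 428, Rpl24 from 235 to 125 and Rpl36a from 140 to 76.2 RPKM. Of 280 tested genes of the short RNA list 4 rose and 3 fell (1 and 3 when adjusted over the list alone, percentile 99.3). Among them Scarna2 rose from 27806 to 114040 RPKM and Snord22 from 883 to 5248, and Scarna13 fell from 246 to 60.4 RPKM. Genes of this list made up 59.6% of the RPKM sum in NLS. Without Mir6236 they made up 57.9% in NLS and 46.9% in noDox. No replication-dependent histone or mitochondrially encoded genes were found under the symbols searched, and these lists were not analysed here.

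**Figure D2:**
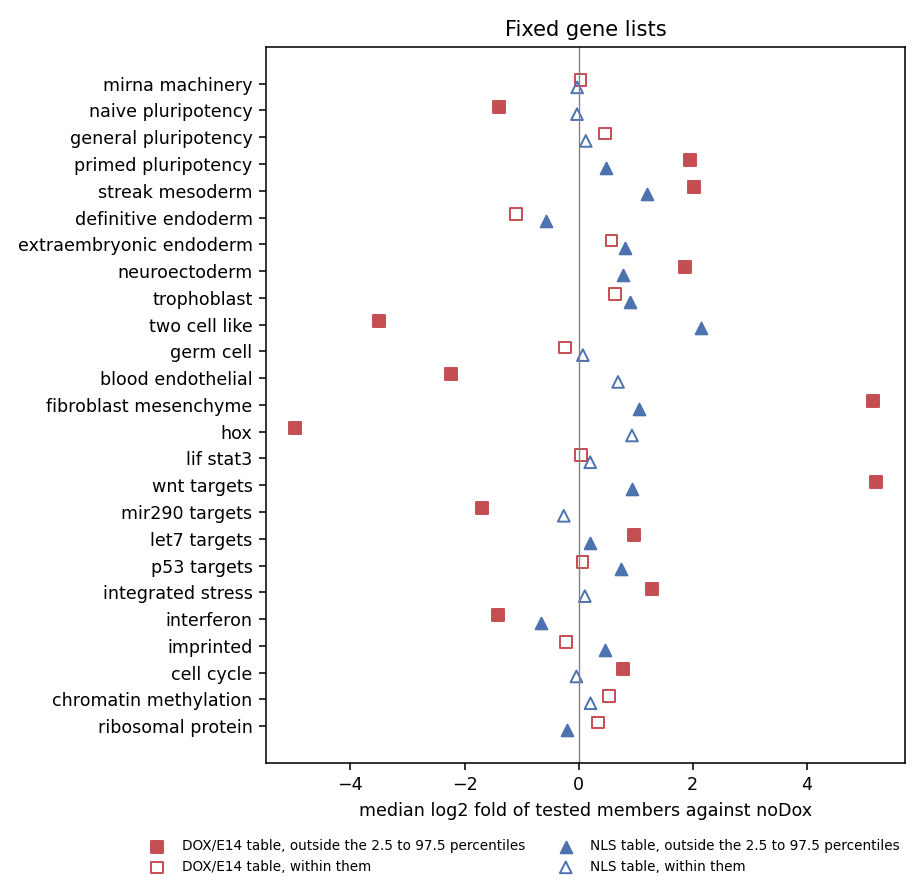
Median log2 fold over noDox of the tested members of each fixed list, squares for the DOX/E14 table and triangles for the NLS table, filled where the median lay outside the central 95% of 10000 matched random lists. Naive pluripotency and miR-290/miR-302 targets lie to the left in the DOX/E14 table, and the 2-cell-like list lies on opposite sides in the 2 tables.

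Both tables share the noDox libraries, so agreement between them arises in part by construction. Of 12072 genes tested in both, 276 rose in both and 471 fell in both. Independent lists of these sizes would share 122 and 163. Unchanged groups simulated against a shared control gave a mean of 18.2 shared calls. There the noise followed the SE used here, while calls were made on the statistic times the square root of 2. The 2 scales differ, so this mean is not a matched yardstick for the observed counts. Among genes called in NLS, 70 rose that fell in DOX/E14 and 10 fell that rose there. Independent lists would give 133 and 149 such opposite calls. Across 10712 genes with at least 1 RPKM in all groups, the correlation of log2 folds was 0.457, with a simulated mean of 0.388 and a simulated maximum of 0.602. The covariance was 0.260, within the simulated range of 0.0931 to 0.464 and near its mean of 0.241, a mean that becomes 0.121 if the SE are smaller by the square root of 2, as most deposited p-values imply. The share of these genes with the same sign was 63.4%, and 63.3% in the simulation. The simulation holds no effect in either group, whereas 6878 of 12382 tested genes were called in the DOX/E14 table. It therefore cannot show how much of the agreement the shared control gives in these data. The controls could not be split, so part of any excess may stem from the shared noDox libraries, and genes are not independent replicates. In genes called in the same direction in both, the NLS fold had a median of 0.654 of the DOX/E14 fold on the log2 scale. These genes had to pass q in NLS, which favours large NLS folds. Over all genes with at least 1 RPKM in both groups, the SD of log2 folds was 0.574 in NLS and 1.07 in DOX/E14.

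**Figure D3:**
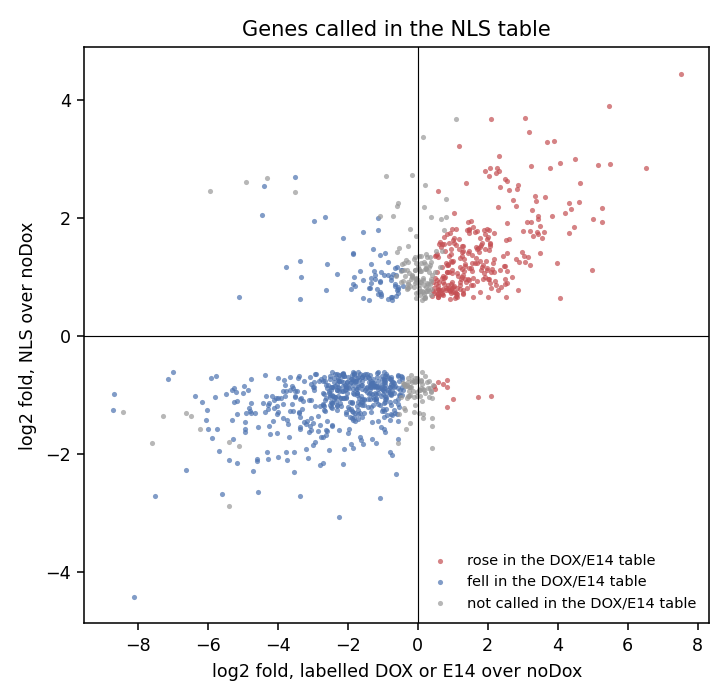
Log2 fold over noDox of 1008 genes called in the NLS table, with the DOX/E14 table on the horizontal and the NLS table on the vertical axis and colours for the call in the DOX/E14 table. Of these genes 536 fell and 284 rose in the DOX/E14 table.

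The difference between the 2 tables was tested directly with a z of the difference of log2 folds. Of 11907 genes 1544 differed at an adjusted p under 0.05, 1165 of them higher in NLS than in DOX/E14 relative to noDox and 379 lower. With an SE at least as large as the deposited p implies, an alternative chosen after seeing the data, 1470 of these genes still differed. With the noDox variance removed 3004 differed, 1968 higher and 1036 lower, and with an SE smaller by the square root of 2, also chosen after seeing the data, 3621 differed, 2196 higher and 1425 lower. On data simulated with the implied SEs of these 11907 genes the test recovered 53 of 100 genes that differed by 2 on the log2 scale and 1 of 100 that differed by 1, with 0 false calls among 11707 unchanged genes. Plagl1 was 7.71 higher in NLS on the log2 scale (SE 0.81) and H19 6.96 higher (SE 0.86). Hhip, Msln, a mesothelial surface protein gene, and Zscan4a were 6.41, 6.39 and 6.22 higher. Grb10 was 3.85 lower in NLS on the log2 scale (difference −3.85, SE 0.47), and Pim2, a serine/threonine kinase gene, had a difference of −3.84 and Mid1 of −4.93. The short RNA genes Mir692-1 and Mir18b had differences of −5.14 and −4.06, but neither passed q < 0.05 in either table. For Mir692-1 the NLS log2 fold of −1.483 was also the most frequent ratio among untested genes of that table (47 of 3509). Its value may thus rest on few reads, which was not tested. Their statistics were larger than their deposited p-values imply (0.24 and 0.416 for Mir692-1, 0.24 and 0.292 for Mir18b), and with the larger SE neither differed (adjusted p under 0.05 not reached).

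By the same test 11 of 17 naive pluripotency genes were higher in NLS than in DOX/E14 and 0 lower, with 11 at an unadjusted p under 0.05 and the same counts when adjusted over the list alone (10 and 0 over all genes with the larger SE). Tbx3 differed by 4.32, Klf4 by 3.98, Prdm14 by 3.48 and Tfcp2l1 by 2.73 on the log2 scale. Of 10 miR-290/miR-302 targets 4 were higher and 0 lower in NLS (6 and 1 when adjusted over the list alone), and 7 had an unadjusted p under 0.05. Of 20 let-7 targets 0 were higher and 5 lower (0 and 8 when adjusted over the list alone), and 9 had an unadjusted p under 0.05. Of 16 p53 targets 4 were higher in NLS and 0 lower (7 and 0 when adjusted over the list alone, 8 at an unadjusted p under 0.05). Of 17 proliferation genes 0 were higher and 3 lower (0 and 5 when adjusted over the list alone, 6 at an unadjusted p under 0.05). Of 4 genes of the 2-cell-like list 3 were higher in NLS, and of 8 interferon-stimulated genes 4 were higher and 1 lower, the same when adjusted over the list alone. Dnmt3b had a difference of −3.42 (SE 0.42), Lin28a of −3.06 (SE 0.63) and Myc of −3.05 (SE 0.67). Because the first table is held under the names DOX and E14, these counts stand only for NLS against whichever of these groups its values belong to. DOX could not be compared with E14.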

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

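The tests of the origin of the DOX/E14 table and of mixing, and the larger SE, were chosen after the values they concern had been seen, while the test of the differences was chosen earlier. The effects of NLS and of DOX/E14 against noDox differed in 1544 genes. The 5 largest differences each way and the named genes called in opposite directions in the 2 tables are given first, as the log2 fold in NLS minus that in DOX/E14. Within the ranking the value was 7.71 for Plagl1, 6.96 for H19, 6.41 for Hhip, 6.39 for Msln and 6.22 for Zscan4a. It was −5.14 for Mir692-1, −4.93 for Mid1, −4.06 for Mir18b, −3.85 for Grb10 and −3.84 for Pim2. Mir692-1 and Mir18b no longer differed with an SE at least as large as their deposited p implies. Ago3 (2.24), Klf4 (3.98) and Tek (3.24) fell in DOX/E14 and rose in NLS, as did H19 and Zscan4a. Other genes named above also differed, among them Tbx3 (4.32), Prdm14 (3.48), Tfcp2l1 (2.73), Mov10 (2.43), Dnmt3b (−3.42), Lin28a (−3.06) and Myc (−3.05).

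The tables named DOX and E14 hold the same numbers, so at least 1 of the names is wrong for its values. If the table held the DOX libraries, Ago1 and Y-linked RNA should stand at the noDox level, since the labels derive DOX from the cells without Argonautes. Ago1 was 1048 times its noDox value, which argues against that. The E14 libraries as the source are consistent with the lowest of the 3 Y-linked genes at 7.66 RPKM, although a Y-linked gene does not identify a line and a different origin of the DOX cells was not tested. If the values are those of the E14 libraries, whether the DOX comparison would look alike stays open.

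Ago1 and Y-linked RNA reached 4.95% (Ago1) and a median of 2.14% (Y-linked genes) of their DOX/E14 values in NLS, while noDox was at or near 0. Reads or cells of the DOX/E14 material in the NLS libraries could give such a level. Of 10 other transcripts below 0.05 RPKM in noDox and at 5 RPKM or more in DOX/E14 (Jarid2, which Cuffdiff skipped, left out), 3 lay below 1% of the DOX/E14 value in NLS, which is 30% (exact 95% interval 6.67 to 65.2%). Another 5 lay at 6.14 to 11.1%, and Gm25500 and Emc8-1190005i06rik lay at 43.5% and 445%, far above what such a share gives, although neither passed q < 0.05 in either table. With so few transcripts, mixing and a true low level cannot be told apart as the source of the Ago1 and Y-linked RNA. Over 12755 tested genes, 46 lay below the lowest level that a share of Ago1's size allows and 80 above the highest level it gives (one-sided, adjusted p under 0.05, with the larger SE). This argues against mixing at that share as the cause for these genes. A larger share was not tested, although 7 of the 10 transcripts reached the Ago1 share or more in NLS. Of 506 called rises, 80 passed this test and the others did not, so mixing is not excluded for the others. Among the others 8 lay below that level or no more than 1 SE above it, including Dnmt3b, Grb10, Acta2 and Sox11. For these 8 mixing and a true rise cannot be told apart because both give such a level. An effect of AGO2 with the nuclear signal stays open as an untested explanation.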

How the results depend on the processing

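No paired analysis was possible because the tables hold only group values, and for the same reason no replicate could be left out. DOX against E14 could not be compared, as both names carry the same values. The count of changed genes in the DOX/E14 table (6878) lay between 5332 and 7240 under the alternatives except for 3897 with an absolute log2 fold of at least 1. The count in NLS (1081) lay between 1074 and 1577 except for 531 at q under 0.01, 642 with the fold limit, 531 with the normal p of the statistic (342 of them among the 1081) and 521 with median-centred folds and that p. The last 2 settings use the statistic as it stands, which is smaller than most p-values imply but larger than others do. With 4.95% or 2.14% of the DOX/E14 value subtracted, NLS gave 1325 and 1322 calls, of which 1017 and 1052 were among the 1081. These calls used the normal p of the statistic scaled by the square root of 2, not the deposited q. That setting gave 1577 calls without subtraction, so subtraction lowered the count. Shared calls (747) became 359 at q under 0.01 and 373 with the fold limit, and stayed at 747 with a floor of 1 RPKM. Genes differing between NLS and DOX/E14 (1544, 75.5% of them higher in NLS) became 887 at an adjusted p under 0.01, 3004 (65.5% higher) with the noDox variance removed and 3621 (60.6% higher) with an SE smaller by the square root of 2, and lay between 1470 and 1850 otherwise. With an SE at least as large as the deposited p implies, 1470 of the 1544 remained, and of the named genes that differed Mir692-1, Mir18b, Copz2, Evx1 and Fbn1 did not. The subtractions, this larger SE, the square root of 2 and the statistics scaled by it were chosen after seeing the data. Stricter limits lower counts by construction, and a smaller SE raises them. List medians kept their side of the limits in 209 of 216 alternatives and none turned. The primitive streak and mesoderm list in NLS no longer lay apart with pseudocount 1 (median 0.53, percentile 96.2) or with the floor (percentile 91.8). Proliferation genes in the DOX/E14 table no longer did so with the floor (percentile 97.45). The definitive endoderm list in the DOX/E14 table came to lie apart (percentiles 1.30 and 2.45 with pseudocount 1 and the floor), DNA methylation genes in NLS did so when centred (97.55), and ribosomal proteins in NLS no longer did with pseudocount 0.1 (2.67). No called fold of a named gene changed sign, and 1 fold below the threshold did (Mcm7 in the DOX/E14 table, when centred). Folds of 67 of 592 named-gene alternatives moved by more than 1 SE. Depth was not recovered from these values, so low genes cannot be given a floor.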

Other observations

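The tests on seed sites and on chromosomes were written before their results were seen, and the comparison of the seed site with a mixture was added afterwards. Transcripts were grouped by 7-base sites in their longest annotated 3' UTR. Folds were taken as residuals on UTR length, GC content and expression, for 9971 genes of the DOX/E14 table and 10583 of the NLS table with at least 1 RPKM in both groups, 91.3% and 91.2% of such genes. Genes with AGCACTT, the site of the miR-290/miR-302 seed, had a median log2 fold of −0.19 in the DOX/E14 table (1770 genes) against 0.079 without it (8201 genes). The residual difference was −0.17. The site ranked 5 of 16349 7-mers from the lowest, a position consistent with loss of microRNA silencing in noDox. GCACTTT, the site of the miR-17/92 seed, ranked 1, and since the sites overlap in 6 bases these ranks are not independent, while the let-7 site CTACCTC ranked 14980 and the miR-124 site GTGCCTT 3213. GTGCAAT, which pairs with the miR-25/92 seed, ranked 2 and was noticed after the ranking.

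In the NLS table AGCACTT ranked 2 of 16360, after GTCCAAG, with a residual difference of −0.057 (SE 0.013), which is consistent with silencing by nuclear AGO2 as a hypothesis. GTCCAAG had the same z (the residual difference over its SE) of −4.26, and AGAGCGC and AGCCCCC followed at −3.75 and −3.71. GCACTTA, which overlaps AGCACTT, ranked 5 at −3.69. The rank thus does not set AGCACTT apart from sequences that were not among the tested sites. The uncorrected medians, −0.025 with the site in 1895 genes and −0.031 without it, lay slightly the other way, so the shift rests on the correction. The miR-17/92 site ranked 2962 there. Scaling the DOX/E14 difference by 4.95% on the log2 scale gave −0.0083. The observed difference was 34.4% of that in the DOX/E14 table and 3.65 SE beyond this scaled value. Mixing adds RPKM rather than log2 folds, so this comparison cannot decide whether mixing is the source of the difference. A cytoplasmic share of the tagged AGO2 was not tested and stays open. Genes sharing a site are not independent replicates.

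A different number of copies of an autosome was looked for as a shift of at least 0.2 in a chromosome's median log2 fold, centred on all autosomes. The largest was 0.153 for chromosome 14 in the DOX/E14 table and 0.093 for chromosome 18 in the NLS table, both below that size. Chromosome 2 in the DOX/E14 table (0.131) and chromosome 1 in the NLS table (0.083) lay above 10000 random sets of genes of the same size. The X chromosome was at 0.047 and 0.065.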
